A study of Mus musculus with 26 samples.

How the data were processed

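RNA-seq was analysed in 18 libraries of 9 groups and ATAC-seq in 8 libraries of 4 groups, 2 libraries per group, all from mouse B-lineage cells. Groups and replicate numbers were taken from the labels. The labels do not say that the replicates came from separate animals or cultures, so p-values measure the spread between these libraries, which may be technical. Replicate 2 without IL-7 is named as small pre-B cells in its title and column, replicate 1 as pre-B cells. Replicate 2 without IL-7 with CXCL12 is named as pre-B cells in its title and small pre-B cells in its column. Both were assigned by media and numbers.

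The RNA-seq values were deposited as 1 table of raw read counts for 23762 gene symbols. Per the labels' protocols, the RNA came from flow-sorted B cells and was made into polyadenylated, stranded libraries. Per the submitters' processing notes, STAR, BWA, Picard, featureCounts, bedtools and MACS2 were used and the genome build was mm9. Their versions and roles, the gene annotation and the strand setting were not given in the sources used here. Counts of overlapping and antisense genes and of genes with near-identical copies are therefore uncertain. The table had 0 columns that belonged to no sample. Symbols were matched to a RefSeq gene table of GRCm38.p6 for pseudogene names and chromosomes alone, and 21903 (92.2%) matched.

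The ATAC-seq values were deposited as peak lists, 1 per library, with a score per peak on the −log10 scale of a p or q value, which of them not being stated. Every score was at least 5 and peak numbers were skipped, so peaks had been removed before deposit. Read shifting, duplicate handling and sequencing depth were not given in the sources used here.

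The counts were fitted as deposited in 1 model of all 18 libraries with 1 mean per group, because 2 libraries per group leave too few degrees of freedom alone. edgeR 4.0.16 (R 4.3.3) was used with TMM scaling, its default filter on low counts and the robust quasi-likelihood test, on 14862 genes. A gene was called at a Benjamini-Hochberg adjusted p under 0.05 within a comparison. The SE of a log2 change was its size over the square root of the F statistic. Totals of 17257914 to 50235192 counts per library set the precision. There were 10 comparisons fixed before the data were examined, and 3 contrasts inside sets of libraries added after. Leaving out a library leaves a group of 1, which is assumed to vary like others.

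The test was tried on simulated counts for CXCL12 without IL-7, with 200 changed genes of 14644 in each of 5 draws. It recovered 15.5%, 47.2% and 76.4% of genes changed 1.5-fold, 2-fold and 4-fold. Of those at 10 CPM or more it recovered 27.4%, 71.7% and 97.4%, a limit chosen after the first simulation was seen. Of 475 calls 13 were false (2.74%), which need not hold where spread differs by group, as here. A raised list of 30 genes was called in 5 of 5 draws and an unchanged one in 0 of 5.

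Gene lists fixed before the data were examined comprised 21 lists of biology, all named with the sorted cells. They were tested with camera (limma 3.58.1) at a preset correlation of 0.01 and again with an estimated correlation, adjusted over the 21 lists. Markers of 11 cell types or states were counted, summed and tested in the same way, adjusted over the 11.

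Named genes followed a rule fixed before the data were examined. It took 26 regulators and markers, of which Igkc is not reported, the 6 called genes with the largest rise and the 6 with the largest fall at a mean log2 CPM of at least 3, and up to 4 members of each described list with the smallest p. In the sorted cells, IL-7 withdrawal, CXCL12 without IL-7 and its difference by genotype all 25 are given. Elsewhere a part of them is. The IgkJ and Igkv segments, Xist, Ddx3y, Gapdh and Rps29 were added after the data were seen.

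ATAC-seq peaks were merged with bedtools 2.31.1 into regions at an overlap of 1 bp. Regions with a peak in both libraries of a group and neither of the other were counted beside the 2 other splits of the same 4 libraries, with no p-value. Peaks were also counted from 67 to 71 Mb of mm9 chromosome 6, which holds Igk. Tables and figures were made with Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9.

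Alternatives fixed beforehand were RLE size factors, no filter, at least 1 CPM in 2 libraries, DESeq2 1.42.0, only the groups compared, a replicate block, a change of at least 2-fold, each library left out in turn, an estimated correlation for lists, and for peaks the higher-scoring part of each list, lists of equal length and an overlap of 50%. Added after the data were seen were close pairs summed to 1 library, the omission of ribosomal protein genes and genes with a named pseudogene, the omission of the 4 Gapdh-high libraries, and peaks without chromosomes 10 to 12.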

Results

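The series addresses how signalling through CXCR4, the receptor of the chemokine CXCL12, relates to recombination of the immunoglobulin kappa light chain locus Igk and to late B lymphopoiesis in the mouse. RNA-seq was measured in 18 libraries that fell into 9 groups of 2. A pair of groups came from sorted small pre-B cells, the stage at which light chain genes are rearranged, labelled wild type or CXCR4-deficient. The remaining 7 groups were cultures labelled by their medium, 5 as pre-B cells: with interleukin 7 (IL-7, the growth factor of B cell progenitors), without IL-7, and without IL-7 with CXCL12, then with both IL-7 and CXCL12 and without IL-7 with CXCL12 and ERK inhibitor II. The last 2 were CXCR4-deficient cells without IL-7, alone or with CXCL12, labelled as small pre-B cells. Of the sufficient cultures, replicate 2 without IL-7 was labelled as small pre-B cells too, and replicate 2 without IL-7 with CXCL12 so in the table but not in its title. Cell stage as labelled therefore goes with genotype only in part. Total counts per library for replicates 1 and 2 were 19297551 and 17678225 in sorted wild-type cells and 32461696 and 27343664 in sorted cells labelled CXCR4-deficient. They were 44244785 and 44727809 with IL-7, 44172189 and 38877140 without IL-7, 43297149 and 17257914 without IL-7 with CXCL12, 46859789 and 50235192 with both factors and 46044096 and 49939490 with the ERK inhibitor. The CXCR4-deficient cultures had 28902098 and 19550744 without IL-7 and 22090638 and 19876401 with CXCL12. ATAC-seq, which marks accessible chromatin, was represented by 8 peak lists of 4 groups of 2. They held 66503 and 57721 peaks in sorted small pre-B cells labelled CXCR4-deficient, 37338 and 31659 with IL-7, 42205 and 35299 without IL-7 and 35800 and 30832 without IL-7 with CXCL12. Below, levels are CPM (counts relative to the TMM-scaled library total) as mean ± SD with n = 2 libraries per group. Each log2 change is given ± SE with the adjusted p of edgeR's quasi-likelihood test.

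Cxcr4 itself was measured first in every library, since it checks the labels. It stood at 943 and 922 CPM in the sorted wild-type libraries, and at 37.2 and 409 CPM in the 2 libraries labelled CXCR4-deficient. In the cultures Cxcr4 was 113 and 112 CPM with IL-7, 169 and 171 without IL-7, 237 and 226 without IL-7 with CXCL12, 288 and 266 with both factors and 309 and 322 with the ERK inhibitor. The cultures labelled CXCR4-deficient had 114 and 130 CPM without IL-7 and 137 and 133 CPM with CXCL12. Each lay below the sufficient libraries of the same medium, and at or above those with IL-7. The deleted part of the gene was not given in the sources used here, and reads from an undeleted part would be counted. Replicate 2 of the sorted libraries labelled CXCR4-deficient therefore goes against its label in part, and every direction drawn from it rests on the label. The same holds for the cultures, which are called CXCR4-deficient or deficient below as they were labelled.

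The libraries also differed by features that their labels do not name. Xist, expressed from the inactive X chromosome of female cells, reached 1251 and 1519.5 CPM with IL-7 and CXCL12 and 1438 and 1454 CPM with the ERK inhibitor. Ddx3y of the Y chromosome was there at 7.0 and 7.02 and 7.73 and 6.83 CPM. In the other cultures Xist was between 0.371 and 1.54 CPM. The sorted libraries labelled CXCR4-deficient held Xist at 31.5 and 2077 and Ddx3y at 87.9 and 0.0725 CPM, and sorted wild-type cells 474 and 410.4 and 139 and 124 CPM. Gapdh, a glycolytic enzyme, and Rps29, a ribosomal protein, were at 1729.8 and 1518 and 871 and 743 CPM with both factors and 1399 and 1556 and 635 and 718 CPM with the ERK inhibitor. The other 14 held at most 12.3 and 2.43 CPM, with Gapdh at 10.9 and 12.3 in sorted wild type. Sorted cells labelled CXCR4-deficient held 2.06 and 2.61. The summed stromal markers were 610.0 ± 211 CPM with IL-7, 1059 ± 7.77 without IL-7 and 2227 ± 18.0 without IL-7 with CXCL12. They were 94.0 ± 3.90 CPM with both factors, 159 ± 7.26 with the ERK inhibitor, and 78.1 ± 11.7 and 85.9 ± 3.30 in the CXCR4-deficient cultures. The summed myeloid markers were 224 ± 46.1, 353 ± 2.68, 887 ± 0.85, 1966 ± 108 and 3708 ± 52.0 CPM in these cultures in the same order. They were 18.8 ± 2.90 and 15.3 ± 0.479 CPM in the CXCR4-deficient cultures. The cultures fell into sets that stood apart: the 3 groups with IL-7, without IL-7 and without IL-7 with CXCL12, the 2 groups with both factors or the ERK inhibitor (below, the Gapdh-high set), and the 2 CXCR4-deficient groups. A comparison across sets cannot be told apart from their difference. Sorted groups, apart in Gapdh, may differ by library too.

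**Figure D1:**
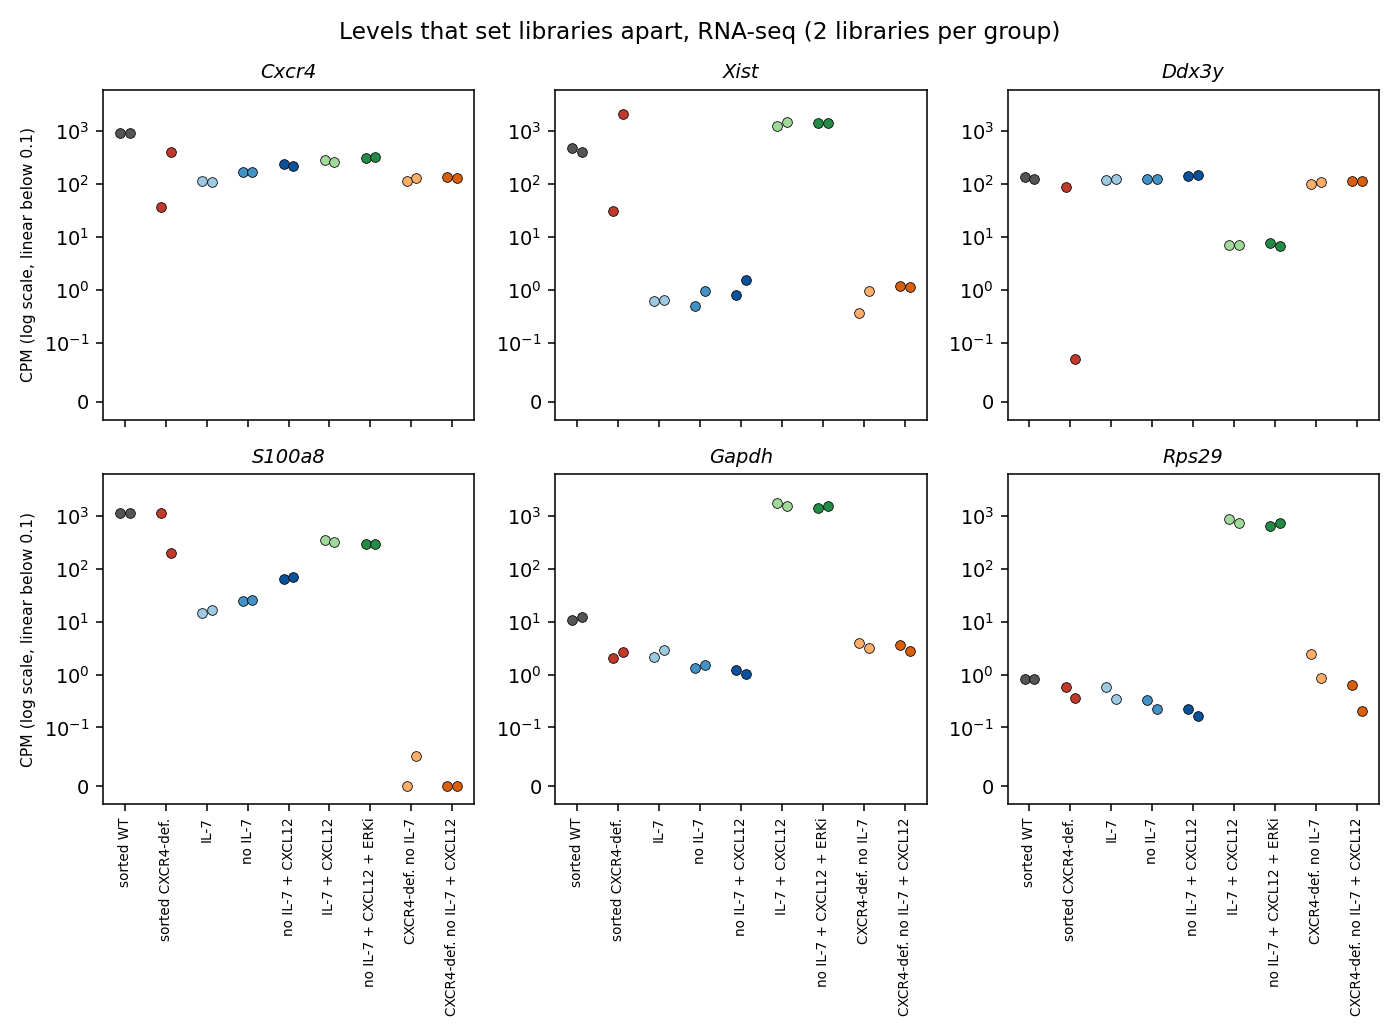
CPM of Cxcr4, Xist, Ddx3y, S100a8, Gapdh and Rps29 in each of the 18 RNA-seq libraries, on a log axis that is linear below 0.1, with 1 point per library and 2 libraries per group. Gapdh and Rps29 lie at 635 CPM or more in the 4 libraries with both factors or with the ERK inhibitor, and at most 12.3 CPM in the other 14.

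To compare sorted small pre-B cells with and without CXCR4, the 2 libraries labelled CXCR4-deficient were set against the 2 wild-type ones (n = 2 each). Transcripts of dividing cells and of the surrogate light chain were higher in the libraries labelled CXCR4-deficient, and Rag1, a subunit of the V(D)J recombinase, was lower. The proliferation marker Mki67 (2037 ± 173 against 483 ± 30.5 CPM, log2 change 2.08 ± 0.15, adjusted p = 6.3e-07) rose. So did the cell cycle regulator Ccnd3 (831 ± 59.0 against 351 ± 31.5 CPM, log2 change 1.24 ± 0.12, adjusted p = 1.2e-05). The surrogate light chain genes Vpreb1 (190.2 ± 71.2 against 34.9 ± 3.95 CPM, log2 change 2.44 ± 0.39, adjusted p = 4.5e-04) and Igll1 (357 ± 139 against 76.4 ± 1.58 CPM, log2 change 2.22 ± 0.27, adjusted p = 6.4e-05) rose as well. Rag1 (1639 ± 160 against 3402 ± 240.0 CPM, log2 change -1.05 ± 0.25, adjusted p = 0.0059) fell. Its partner Rag2 (164 ± 4.47 against 159.9 ± 4.66 CPM, log2 change 0.04 ± 0.08, adjusted p = 0.76) did not pass the test. Cxcr4 (223 ± 263 against 932 ± 14.9 CPM, log2 change -2.06 ± 0.67, adjusted p = 0.031) was lower, and the call ended without wild-type replicate 1 or 2 (adjusted p 0.082 to 0.099). Its change was -1.20 without replicate 1 and -4.65 without replicate 2 labelled CXCR4-deficient.

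Among the regulators named before the data were examined, Foxo1 (-0.43 ± 0.09), Ikzf3 (-0.89 ± 0.28), Spib (-0.38 ± 0.08), Brwd1 (-0.43 ± 0.10), Il2ra (-1.09 ± 0.10), Ccnd1 (-2.10 ± 0.40), Egr1 (-1.74 ± 0.45) and Dusp6 (-0.86 ± 0.16) fell in sorted cells labelled CXCR4-deficient. Here and below, the values after a gene are its log2 change ± SE. Il2ra encodes CD25, Dusp6 a phosphatase that limits ERK, and Brwd1 a chromatin reader of late B cell development. Id3 (1.28 ± 0.25) and Cish (0.82 ± 0.12) rose. The call of Ikzf3 ended without any 1 of the 4 libraries and that of Brwd1 without wild-type replicate 1. Egr1 changed by -1.03 and -3.24 without replicates 1 and 2 labelled CXCR4-deficient, and Ccnd1 by -3.17 without replicate 1. Irf4 (-0.23 ± 0.09), Irf8 (0.10 ± 0.08), Pax5 (0.23 ± 0.23), Ikzf1 (-0.21 ± 0.15), Myc (0.09 ± 0.08), Ccnd2 (-0.45 ± 0.18), Il7r (-0.20 ± 0.11) and Bcl6 (-0.47 ± 0.17) did not pass. Without replicate 1 labelled CXCR4-deficient Bcl6 did (-0.70, adjusted p = 0.018). The calls of Cxcr4 and Ikzf3 also ended with close pairs of libraries summed to 1 and without the 4 Gapdh-high libraries, and those of Cxcr4, Egr1, Dusp6 and Ighg3 with these libraries fitted alone. The 6 largest rises among well expressed genes were H2afx (4.01 ± 0.33), Ctse (3.81 ± 0.13), Itga5 (3.58 ± 0.17), Neurl1b (3.52 ± 0.14), Celsr1 (3.48 ± 0.30) and Hjurp (3.40 ± 0.10). The 6 largest falls were Ighg3 (-6.57 ± 0.75), Igkv3-4 (-4.91 ± 0.26), Igj (-4.90 ± 0.38), Igkv6-15 (-4.02 ± 0.27), Rps25 (-3.95 ± 0.29) and Rps7 (-3.86 ± 0.25). Ighg3 and Igj belong to antibody-secreting cells, and the Igkv segments and ribosomal protein genes share reads with near-identical copies, so their values are uncertain.

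Genes of the dividing cell moved together in this comparison. For each list, here and below, the members called higher and lower over all genes are given, and in brackets those adjusted over the list alone. The adjusted p after a list that camera called is that with an estimated correlation, and where it is 0.05 or more the call was lost. Of the cell cycle genes, 43 of 45 S phase genes were higher and 0 lower [43 and 0] (adjusted p = 0.0021). They included Rad51ap1 (1.71 ± 0.08), Rrm2 (1.74 ± 0.09) and Ccne2 (1.53 ± 0.09). G2 and M phase genes gave 52 and 1 of 54 [52 and 1] (adjusted p = 0.0021). Among them were Aurkb (2.18 ± 0.08), Kif2c (2.59 ± 0.10) and Ndc80 (2.07 ± 0.09). D cyclin and CDK inhibitor genes gave 11 and 3 of 18 [11 and 5] (adjusted p = 0.036). The risers held Cdkn2c (1.73 ± 0.08) and Cdkn1a (1.23 ± 0.09), which restrain the cycle, and Cdk4 (0.92 ± 0.12), which drives it. NF-kB targets gave 0 and 11 of 18 [0 and 11] (adjusted p = 0.028). Examples were Nfkbiz (-0.95 ± 0.10), Pim2 (-1.01 ± 0.12) and Cd40 (-1.73 ± 0.21). Late B cell maturation genes gave 1 and 20 of 30 [1 and 22] (adjusted p = 0.071). They included Cd83 (-2.56 ± 0.15), H2-Ob (-1.36 ± 0.10) and Cr2 (-3.74 ± 0.32). FOXO targets gave 0 and 10 of 25 [0 and 13] (adjusted p = 0.20), with Btg1 (-0.75 ± 0.10) and Tob1 (-1.0 ± 0.15). Chemokine receptor, adhesion and migration genes gave 1 and 12 of 33 [1 and 12] (adjusted p = 0.12). Among them were Ccr6 (-3.43 ± 0.45) and Ccr9 (-2.79 ± 0.38). Chromatin regulators gave 10 and 2 of 28 [11 and 2] (adjusted p = 0.76). Examples were Uhrf1 (1.18 ± 0.08) and Smc1a (0.73 ± 0.09).

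The remaining lists were not called by camera between the sorted groups. Members higher and lower were for ERK immediate early and feedback genes 2 and 10 of 29 [2 and 10]. They included Egr3 (-2.47 ± 0.45) and Nr4a1 (0.93 ± 0.10). For V(D)J recombination genes 5 and 5 of 15 [5 and 5], the risers held Dntt (2.02 ± 0.19) and Poll (1.47 ± 0.18). They were for B-lineage transcription factors 5 and 6 of 26 [6 and 8], with a median log2 change of -0.27 and a mean of 0.00. For pre-BCR and proximal signalling genes they were 4 and 5 of 17 [5 and 5], with a median of -0.09 and a mean of 0.15. For metabolism they were glycolysis genes 5 and 4 of 22 [5 and 4], oxidative phosphorylation genes 2 and 0 of 36 [1 and 0] and cholesterol synthesis genes 2 and 3 of 20 [2 and 3]. The others were BCL2 family genes 3 and 6 of 15 [4 and 6], interferon response genes 2 and 7 of 28 [2 and 7], p53 targets 2 and 6 of 20 [2 and 6] and STAT5 and IL-7 targets 4 and 5 of 17 [5 and 6]. Last came MYC and ribosome biogenesis genes 3 and 7 of 38 [3 and 6] and amino acid and unfolded protein stress genes 5 and 6 of 26 [5 and 6].

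Markers of other stages and cell types were counted beside the maturation and cell cycle genes. Of the 13 mature B cell markers 9 are themselves in the biology lists, and of the 14 pro-B and progenitor markers 5. Their shifts are therefore no separate support for those of the lists. Mature B cell markers (0 higher and 11 lower of 13) summed to 862 ± 50.9 CPM in sorted cells labelled CXCR4-deficient against 1655 ± 47.2 in wild type. Pro-B and progenitor markers (8 higher and 1 lower of 13) summed to 1535 ± 382 against 561 ± 25.8 CPM. Plasma cell markers gave 0 higher and 4 lower of 9, NK cell markers 0 and 4 of 10, plasmacytoid dendritic cell markers 0 and 4 of 10 and T cell markers 3 and 4 of 14. Myeloid markers gave 3 and 0 of 20, erythroid markers 2 and 0 of 9, megakaryocyte markers 0 and 1 of 7, stromal markers 0 and 1 of 14 and RNA quality and stress genes 0 and 1 of 10. Camera called the mature B, pro-B, plasma, NK and plasmacytoid dendritic cell markers, and with an estimated correlation the mature B cell markers (adjusted p = 0.019) alone. The myeloid sum ran from 1276 to 7419 CPM in libraries labelled CXCR4-deficient (S100a8 at 1122 in replicate 1, 193 in 2) and 5919 to 5966 in wild type. Over all 14862 genes tested, 5079 were called, 2462 higher and 2617 lower (2923 and 2494 with these libraries fitted alone, 1191 and 1146 at 2-fold or more), and without wild-type replicate 1 the count was 3137.

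To follow the loss of IL-7, cultures without IL-7 were compared with cultures with it (n = 2 each). Genes of ribosome production, glycolysis and the IL-7 response were lower without IL-7, and both Rag genes were higher. Rag1 (206 ± 1.36 against 99.4 ± 9.26 CPM, log2 change 1.05 ± 0.25, adjusted p = 0.017) and Rag2 (37.1 ± 0.338 against 16.6 ± 1.02 CPM, log2 change 1.16 ± 0.08, adjusted p = 9.3e-06) rose. Irf4 (381 ± 6.81 against 229.6 ± 7.76 CPM, log2 change 0.73 ± 0.10, adjusted p = 4.4e-04), a transcription factor of light chain rearrangement, was higher as well. So was Il7r (231 ± 6.83 against 94.6 ± 4.07 CPM, log2 change 1.29 ± 0.11, adjusted p = 3.6e-05), the IL-7 receptor. Myc (84.3 ± 0.271 against 161 ± 3.62 CPM, log2 change -0.94 ± 0.08, adjusted p = 2.1e-05) and Ccnd2 (211 ± 3.57 against 457 ± 9.21 CPM, log2 change -1.12 ± 0.18, adjusted p = 0.0016) fell. Cish (29.4 ± 0.745 against 76.3 ± 3.81 CPM, log2 change -1.37 ± 0.10, adjusted p = 1.1e-05), a feedback inhibitor induced by STAT5, fell too. The call of Rag1 ended without any 1 of the 4 libraries (adjusted p 0.08 to 0.12). Its log2 changes without 1 library lay between 0.96 and 1.15.

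Ikzf1 (0.54 ± 0.15), Brwd1 (0.53 ± 0.10), Bcl6 (0.73 ± 0.18) and Dusp6 (0.82 ± 0.16) also rose with the loss of IL-7 and Il2ra (-0.33 ± 0.10) fell. The calls of Ikzf1, Bcl6 and Il2ra ended without any 1 of the 4 libraries. The call of Brwd1 ended without replicate 2 of either group and that of Dusp6 without replicate 1 of either group. Cxcr4 (0.59 ± 0.65), Irf8 (0.17 ± 0.08), Foxo1 (0.29 ± 0.09), Pax5 (0.27 ± 0.23), Ikzf3 (0.39 ± 0.28) and Spib (0.13 ± 0.08) did not pass. Nor did Ccnd1 (0.75 ± 0.34), Ccnd3 (-0.26 ± 0.12), Mki67 (0.21 ± 0.14), Vpreb1 (-0.05 ± 0.36), Igll1 (-0.19 ± 0.26), Egr1 (0.73 ± 0.44) and Id3 (-0.18 ± 0.24). The 6 largest rises were Ctgf (2.00 ± 0.27), Lgr5 (1.89 ± 0.13), Clic5 (1.86 ± 0.22), Spns3 (1.80 ± 0.13), Slc12a3 (1.79 ± 0.13) and Cyr61 (1.73 ± 0.27). The 6 largest falls were Lta (-3.44 ± 0.34), Gldc (-2.81 ± 0.31), Vat1l (-2.17 ± 0.14), Nov (-2.16 ± 0.27), Tnfsf11 (-2.08 ± 0.15) and Tubb3 (-2.08 ± 0.12). Of the lists, 0 of 38 MYC and ribosome biogenesis genes were higher and 33 lower [0 and 36] (adjusted p = 0.0027). Among them were Gnl3 (-1.14 ± 0.06), Rrp12 (-1.0 ± 0.07) and Hspd1 (-0.93 ± 0.07). Glycolysis genes gave 0 and 14 of 22 [0 and 16] (adjusted p = 0.0051). Examples were Pfkl (-1.28 ± 0.12) and Ldha (-1.35 ± 0.14). STAT5 and IL-7 targets gave 2 and 9 of 17 [2 and 11] (adjusted p = 0.0051), with Bcl2 (-1.88 ± 0.14), an inhibitor of cell death. Calls were lost for amino acid and unfolded protein stress genes 1 and 10 of 26 [1 and 12] (adjusted p = 0.058), with Xbp1 (-1.18 ± 0.08) and Slc7a5 (-0.96 ± 0.13) and Herpud1 (0.72 ± 0.08). They were also lost for S phase genes 0 and 8 of 45 [0 and 10] (adjusted p = 0.051), with Cdca7 (-0.69 ± 0.08), and for oxidative phosphorylation genes 0 and 3 of 36 [0 and 1] (adjusted p = 0.51), with Atp5b (-0.52 ± 0.09).

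Several lists held more members higher than lower without IL-7, each of them a camera call that was lost with an estimated correlation. Members higher and lower were for V(D)J recombination genes 6 and 1 of 15 [6 and 1] (adjusted p = 0.068), with the end joining enzymes Polm (1.66 ± 0.13) and Lig4 (0.74 ± 0.08). For NF-kB targets 8 and 1 of 18 [11 and 2] (adjusted p = 0.058), examples were Nfkbie (0.67 ± 0.09), Relb (0.96 ± 0.14) and Nfkbia (0.83 ± 0.12) and Tnf (-1.65 ± 0.21). They were for FOXO targets 9 and 2 of 25 [13 and 2] (adjusted p = 0.058), with Ccng2 (0.72 ± 0.08), and for B-lineage transcription factors 7 and 0 of 26 [10 and 0] (adjusted p = 0.25), with Myb (0.78 ± 0.07). Numbers were for late B cell maturation genes 6 and 2 of 30 [7 and 2] (adjusted p = 0.28) and for ERK immediate early and feedback genes 6 and 1 of 29 [11 and 1] (adjusted p = 0.30). Stromal markers summed to 1059 ± 7.77 against 610.0 ± 211 CPM in these libraries, beside the rises of Ctgf and Cyr61, which stromal cells express. With close pairs summed the calls of Rag1, Ccnd2, Ikzf1, Brwd1, Bcl6, Dusp6, Il2ra, Cyr61 and Atp5b ended, without the 4 Gapdh-high libraries those of Rag1, Ikzf1, Bcl6 and Il2ra, without a filter or with a replicate block that of Il2ra, and with these libraries fitted alone those of Ctgf and Cyr61. In all, 1758 genes were called, 832 higher and 926 lower. The split turned with RLE (910 and 882), without a filter (834 and 702), with DESeq2 (1453 and 1223) and at 2-fold or more (216 and 174). The count was 739 and 851 without replicates 1 and 2 with IL-7, and 589 and 592 without those lacking it. The close pairs, those without IL-7 and without IL-7 with CXCL12, differed by little more than counting noise (chi-square per gene 1.5 and 1.3). With them summed 355 genes were called.

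For the response to CXCL12 without IL-7, cultures with CXCL12 were compared with those without either factor (n = 2 each). Each group is a close pair and may hold technical repeats. Genes of DNA replication and mitosis were lower with CXCL12, and both Rag genes, several B cell regulators and NF-kB targets were higher. Rag1 (431 ± 3.87 against 206 ± 1.36 CPM, log2 change 1.07 ± 0.25, adjusted p = 0.007) and Rag2 (52.5 ± 1.40 against 37.1 ± 0.338 CPM, log2 change 0.50 ± 0.08, adjusted p = 4.5e-04) rose. Irf4 (737 ± 21.6 against 381 ± 6.81 CPM, log2 change 0.95 ± 0.10, adjusted p = 1.5e-05) and Brwd1 (56.4 ± 0.337 against 23.2 ± 1.31 CPM, log2 change 1.28 ± 0.10, adjusted p = 2.5e-06) rose along with them. Il2ra (94.1 ± 1.33 against 30.2 ± 0.875 CPM, log2 change 1.64 ± 0.10, adjusted p = 3.2e-07) rose as well. Myc (26.4 ± 1.75 against 84.3 ± 0.271 CPM, log2 change -1.67 ± 0.08, adjusted p = 6.5e-08) and Ccnd3 (323 ± 3.96 against 795 ± 8.29 CPM, log2 change -1.30 ± 0.12, adjusted p = 1.1e-05) fell. Mki67 (777 ± 3.70 against 2007 ± 16.6 CPM, log2 change -1.37 ± 0.14, adjusted p = 2.1e-05) and Cish (4.54 ± 0.352 against 29.4 ± 0.745 CPM, log2 change -2.69 ± 0.11, adjusted p = 3.9e-08) were lower too. The call of Rag1 ended without either replicate lacking CXCL12.

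With CXCL12, Irf8 (0.36 ± 0.08), Foxo1 (0.54 ± 0.09), Spib (0.88 ± 0.08), Ccnd1 (1.22 ± 0.34), Il7r (0.39 ± 0.11), Bcl6 (1.54 ± 0.18) and Dusp6 (1.10 ± 0.16) also rose. Ccnd2 (-0.97 ± 0.18) and Igll1 (-1.35 ± 0.27) fell. The calls of Ccnd1 and Il7r ended without any 1 of the 4 libraries, and that of Irf8 without either replicate lacking CXCL12 or replicate 1 with it. Cxcr4 (0.44 ± 0.65), Pax5 (0.24 ± 0.23), Ikzf1 (0.09 ± 0.15), Ikzf3 (0.72 ± 0.28), Vpreb1 (-0.72 ± 0.37), Egr1 (0.93 ± 0.44) and Id3 (0.03 ± 0.24) did not pass. The 6 largest rises were Fosb (2.94 ± 0.57), Igkv1-135 (2.61 ± 0.12), Cd83 (2.33 ± 0.13), Bcl3 (2.19 ± 0.18), H2-Q5 (2.15 ± 0.23) and Cacna1e (2.09 ± 0.30). Of these Igkv1-135 and H2-Q5 have near-identical copies and are uncertain. The 6 largest falls were Gldc (-5.73 ± 0.37), Crhbp (-5.71 ± 0.34), Clgn (-5.16 ± 0.12), Myl10 (-3.45 ± 0.35), Ttll11 (-3.10 ± 0.20) and Vpreb2 (-2.98 ± 0.31). Of the lists, 0 of 45 S phase genes were higher and 45 lower [0 and 45] (adjusted p = 2.8e-04). They included Cdca7 (-2.23 ± 0.08), Mcm6 (-1.76 ± 0.07), Uhrf1 (-1.87 ± 0.08) and Exo1 (-1.72 ± 0.08). G2 and M phase genes gave 0 and 53 of 54 [0 and 54] (adjusted p = 7.3e-04). Among them were Nusap1 (-1.81 ± 0.09), Aurkb (-1.53 ± 0.08) and Ttk (-1.72 ± 0.10). D cyclin and CDK inhibitor genes gave 3 and 9 of 18 [3 and 10] (adjusted p = 0.016), with Cdkn2c (-1.04 ± 0.08), E2f2 (-0.61 ± 0.07) and E2f1 (-1.13 ± 0.14). Cholesterol synthesis genes gave 0 and 6 of 20 [0 and 7] (adjusted p = 0.016). An example was Sqle (-0.61 ± 0.09).

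Going up with CXCL12, 13 of 18 NF-kB targets were higher and 1 lower [13 and 1] (adjusted p = 0.0037). They included Nfkbie (1.5 ± 0.09), Nfkb2 (1.63 ± 0.11) and Birc3 (1.25 ± 0.09). The call was lost in each other list with more members higher than lower. Members higher and lower were for late B cell maturation genes 17 and 1 of 30 [19 and 1] (adjusted p = 0.067), with Ighd (1.03 ± 0.09) and Cxcr5 (-1.42 ± 0.16). They were for FOXO targets 13 and 0 of 25 [13 and 1] (adjusted p = 0.11), with Btg1 (1.09 ± 0.10), S1pr1 (0.94 ± 0.12) and Ccr7 (0.90 ± 0.13). For chemokine receptor, adhesion and migration genes they were 12 and 1 of 33 [12 and 1] (adjusted p = 0.08), with Rgs1 (1.86 ± 0.24) and Cnr2 (1.74 ± 0.24). Then came ERK immediate early and feedback genes 12 and 1 of 29 [15 and 1] (adjusted p = 0.24), with Nr4a1 (0.54 ± 0.09), and B-lineage transcription factors 9 and 2 of 26 [10 and 2] (adjusted p = 0.44), with Myb (0.87 ± 0.07). It was also lost in the lists that leaned lower, for MYC and ribosome biogenesis genes 0 and 17 of 38 [0 and 17] (adjusted p = 0.068), with Pa2g4 (-0.89 ± 0.08) and Ncl (-0.77 ± 0.09). So it was for chromatin regulators 1 and 13 of 28 [1 and 14] (adjusted p = 0.44), with Smc1a (-0.96 ± 0.09) and Rad21 (-1.05 ± 0.14). The same applied to amino acid and unfolded protein stress genes 4 and 9 of 26 [4 and 9] (adjusted p = 0.31) and oxidative phosphorylation genes 0 and 4 of 36 [0 and 4] (adjusted p = 0.55). Camera did not call the V(D)J recombination genes, 4 and 5 of 15 [5 and 5], which held Polm (1.64 ± 0.12) and Hmgb1 (-0.80 ± 0.10) and Xrcc5 (-0.95 ± 0.12). Hmgb1 has many near-identical copies and is uncertain.

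Stromal markers (6 higher and 0 lower of 14) moved beside the ERK genes and Fosb with CXCL12, and mature B cell markers (6 higher and 0 lower of 13) beside the maturation genes. Myeloid markers gave 2 and 0 of 20, T cell markers 1 and 5 of 14 and RNA quality and stress genes 4 and 3 of 10. Camera called the mature B cell (adjusted p = 0.0029, 0.12 with an estimated correlation) and myeloid markers (0.0096 and 0.67). In 2 further lists that camera did not call, the median and mean log2 change differed in sign, with 0.25 and -0.12 for pre-BCR and proximal signalling genes and -0.06 and 0.14 for BCL2 family genes. With close pairs summed the calls of Rag1, Irf8, Foxo1, Ccnd1, Il7r, Ccnd2, Igll1, Fosb and Nr4a1 ended, without the 4 Gapdh-high libraries those of Irf8, Ccnd1 and Il7r, and without genes that have named copies that of Il7r. Over all genes 4543 were called, 2574 higher and 1969 lower. The split turned in several alternatives: with these libraries fitted alone 5309 were higher and 5481 lower, without genes that have named copies 1922 and 2455, without the 4 Gapdh-high libraries 1391 and 1980, and with close pairs summed 412 and 737. The count was 2336 and 2257 without replicates 1 and 2 lacking CXCL12, and 2316 and 2573 without those with it, with more lower than higher in the first 3.

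**Figure D2:**
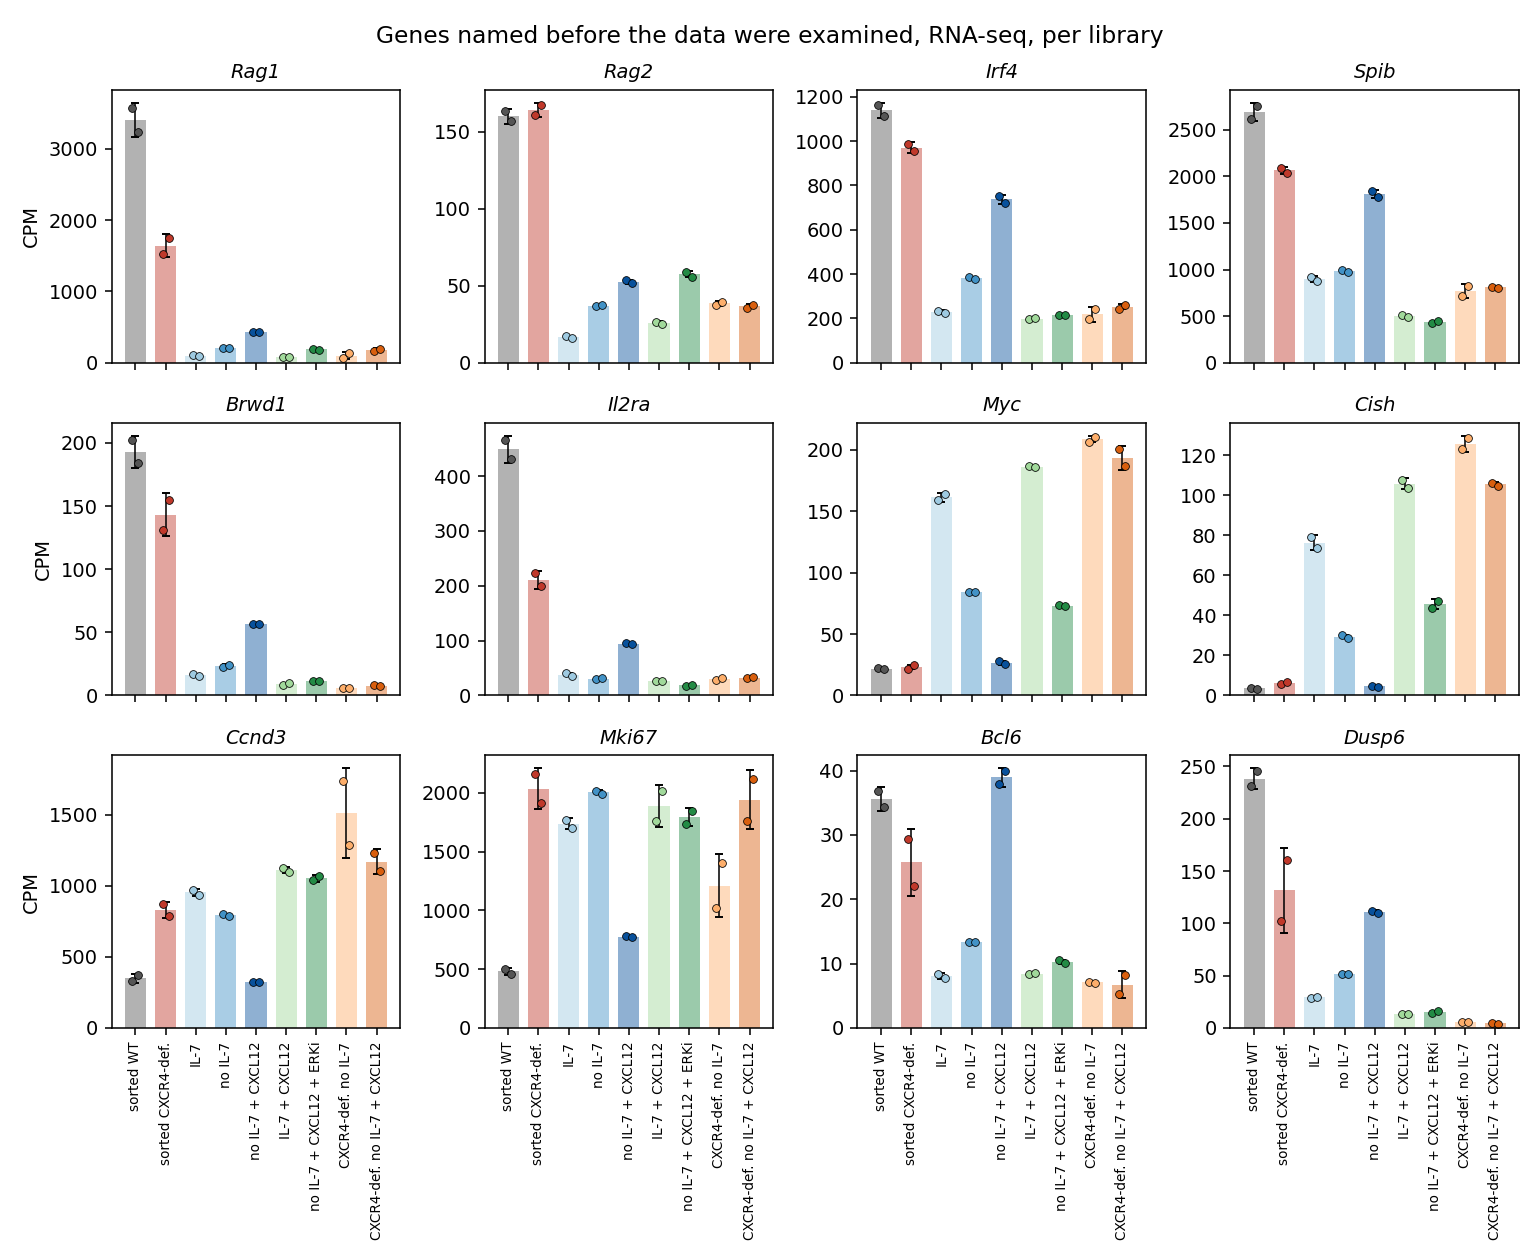
CPM of 12 genes in 9 groups of RNA-seq libraries, with bars for means, points for the 2 libraries of a group and error bars for SD. Rag1, Irf4, Spib, Brwd1, Il2ra, Bcl6 and Dusp6 are higher, and Myc, Cish, Ccnd3 and Mki67 lower, without IL-7 with CXCL12 than without IL-7.

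Whether the response to CXCL12 needed the receptor was examined in CXCR4-deficient cultures without IL-7 (n = 2 each). Rag1 (179.7 ± 26.2 against 96.5 ± 49.9 CPM, log2 change 0.90 ± 0.25, adjusted p = 0.023) was called higher with CXCL12. So were Ikzf1 (0.43 ± 0.15), Ikzf3 (1.22 ± 0.29), Brwd1 (0.39 ± 0.12) and Mki67 (0.68 ± 0.14). Pax5 (-0.75 ± 0.23), Vpreb1 (-1.32 ± 0.37), Igll1 (-0.79 ± 0.26), Ccnd3 (-0.37 ± 0.12) and Id3 (-0.85 ± 0.24) were called lower. Myc (194 ± 9.81 against 209 ± 2.78 CPM, log2 change -0.11 ± 0.08, adjusted p = 0.29) and Irf4 (253 ± 11.7 against 219 ± 33.7 CPM, log2 change 0.20 ± 0.09, adjusted p = 0.11) did not pass. Nor did Il2ra (32.4 ± 2.09 against 29.4 ± 3.06 CPM, log2 change 0.14 ± 0.10, adjusted p = 0.31). The 6 largest rises were Zbed6 (2.17 ± 0.70), Cbl (2.16 ± 0.48), Lmbrd2 (2.09 ± 0.54), Nlrc3 (2.04 ± 0.64), Xrn1 (1.96 ± 0.59) and Hmbox1 (1.96 ± 0.38). The 6 largest falls were Rpl13 (-2.43 ± 0.58), Scand1 (-2.30 ± 0.70), Atp5e (-2.19 ± 0.53), Mrpl52 (-2.09 ± 0.51), Mir703 (-2.07 ± 0.47) and Rpl37a (-2.06 ± 0.50). Of the lists, 0 of 36 oxidative phosphorylation genes were higher and 33 lower [0 and 33] (adjusted p = 0.55), and 17 of 28 chromatin regulators were higher and 3 lower [20 and 4] (adjusted p = 0.55). Among them were Ep300 (0.94 ± 0.19) and Arid1a (0.49 ± 0.11). No list kept its call with an estimated correlation. The 2 libraries without CXCL12 differed more than any other pair (chi-square per gene 284), with ribosomal protein genes at 64803 CPM in one and 22369 in the other.

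The 5020 calls of this comparison, 1906 higher and 3114 lower, rested on the spread shared with all 18 libraries. With these 4 libraries fitted alone edgeR called 0 genes (261 at an unadjusted p under 0.05), and 0 also with close pairs summed or without the 4 Gapdh-high libraries. The calls of Ikzf1 and Brwd1 ended without a filter too. DESeq2 on all libraries called 6302. Leaving out replicate 1 or 2 without CXCL12 gave 1250 (873 higher and 377 lower) or 8602 calls. Leaving out replicate 1 or 2 with CXCL12 gave 31 or 0 by edgeR, the latter with 4040 at an unadjusted p under 0.05. Either omission ended the call of every gene named above as higher or lower (adjusted p 0.058 to 0.24). Without replicate 1 lacking CXCL12 the calls of Ikzf1, Brwd1, Pax5, Vpreb1, Igll1, Ccnd3, Id3, Nlrc3, Rpl13, Scand1, Mrpl52, Mir703 and Rpl37a ended as well (adjusted p 0.053 to 0.59). The change of Rag1 was 0.46 without that library and 1.56 without replicate 2 lacking CXCL12, and without the latter Irf4 (0.37, adjusted p = 1.1e-04) and Il2ra (0.25, adjusted p = 0.045) passed. Over these omissions of a library lacking CXCL12 the 6 largest rises lay between 1.10 and 5.15, and without replicate 1 the 6 largest falls lay between -1.04 and -0.41.

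The difference between the responses of CXCR4-sufficient and CXCR4-deficient cultures was tested as an interaction. Log2 changes with CXCL12 in sufficient and deficient cultures differed for Rag2 (0.50 and -0.07, difference 0.57 ± 0.11, adjusted p = 0.0031) and Irf4 (0.95 and 0.20, difference 0.75 ± 0.13, adjusted p = 0.002). The same held for Il2ra (1.64 and 0.14, difference 1.5 ± 0.14, adjusted p = 1.8e-05) and Bcl6 (1.54 and -0.08, difference 1.61 ± 0.26, adjusted p = 9.6e-04). They also differed for Myc (-1.67 and -0.11, difference -1.56 ± 0.11, adjusted p = 2.8e-06) and Mki67 (-1.37 and 0.68, difference -2.05 ± 0.20, adjusted p = 2.3e-05). Further differences were those of Ccnd3 (-1.30 and -0.37, difference -0.93 ± 0.17, adjusted p = 0.0027) and Cish (-2.69 and -0.25, difference -2.43 ± 0.14, adjusted p = 1.2e-06). For Rag1 the changes were 1.07 and 0.90, and the difference of 0.17 ± 0.35 did not pass (adjusted p = 0.78). Without replicate 1 of the deficient cultures lacking CXCL12 it was 0.51, and without replicate 2 it was -0.49.

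Of the other regulators, Irf8 (0.45 ± 0.12), Pax5 (0.99 ± 0.33), Spib (0.81 ± 0.12), Brwd1 (0.89 ± 0.15) and Dusp6 (1.47 ± 0.25) had a more positive response in sufficient cultures. Ccnd2 (-1.40 ± 0.25) had a more negative one. Cxcr4 (0.30 ± 0.91), Foxo1 (0.32 ± 0.13), Ikzf1 (-0.34 ± 0.21), Ikzf3 (-0.50 ± 0.40), Ccnd1 (0.78 ± 1.77), Il7r (0.15 ± 0.16), Vpreb1 (0.60 ± 0.52), Igll1 (-0.56 ± 0.37), Egr1 (1.26 ± 0.67) and Id3 (0.88 ± 0.34) did not pass. The call of Pax5 ended without any 1 of the 8 libraries but replicate 2 of the deficient cultures lacking CXCL12. That of Irf8 ended without any 1 sufficient library or replicate 2 of the deficient ones with CXCL12. Without replicate 1 of the deficient cultures lacking CXCL12 the difference was 0.26 for Pax5, 0.31 for Foxo1 and -1.19 for Igll1. Without replicate 2 it was -0.70 for Ikzf1, -1.25 for Ikzf3, 1.19 for Vpreb1 and 1.25 for Id3. The calls of Rag2, Irf8, Pax5, Scand1 and S100a6 ended with close pairs summed and with the 8 libraries fitted alone, the latter ending those of Irf4 and Ccnd3 too. Without the 4 Gapdh-high libraries those of Irf8, Pax5 and S100a6 ended, without a filter those of Pax5 and S100a6, and with a replicate block or without genes that have named copies that of Pax5.

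Lists called in this difference had the sign of the response of sufficient cultures. For replication 0 of 45 S phase genes were more positive and 42 more negative [0 and 43] (adjusted p = 6.4e-04), with Cdca7 (-2.13 ± 0.11) and Uhrf1 (-2.17 ± 0.11). The numbers were for G2 and M phase genes 0 and 49 of 54 [0 and 50] (adjusted p = 0.0014). Examples were Nusap1 (-1.94 ± 0.13) and Ttk (-1.87 ± 0.13). For NF-kB targets they were 12 and 1 of 18 [14 and 1] (adjusted p = 0.003). They included Cd83 (3.23 ± 0.25), Nfkbie (1.61 ± 0.13) and Relb (2.59 ± 0.20). They were for cholesterol synthesis genes 0 and 9 of 20 [0 and 10] (adjusted p = 0.027) and D cyclin and CDK inhibitor genes 2 and 7 of 18 [2 and 10] (adjusted p = 0.032). Among them were Rbl1 (-1.97 ± 0.24) and Cdk6 (-1.95 ± 0.25). Calls were lost for late B cell maturation genes 20 and 1 of 30 [20 and 1] (adjusted p = 0.052) and chromatin regulators 1 and 13 of 28 [1 and 15] (adjusted p = 0.31). It was also so for ERK immediate early and feedback genes 9 and 1 of 29 [9 and 1] (adjusted p = 0.31) and FOXO targets 10 and 2 of 25 [13 and 3] (adjusted p = 0.35). Mature B cell markers gave 5 and 0 of 13 (adjusted p = 0.019, 0.25 with an estimated correlation), T cell markers 0 and 4 of 14 and RNA quality genes 4 and 1 of 10. The 6 largest positive differences were Scand1 (3.81 ± 0.96), H2-K2 (3.33 ± 0.41), Jund (3.18 ± 0.55), S100a6 (2.62 ± 0.86), Rpl3l (2.61 ± 0.46) and Relb (2.59 ± 0.20). The 6 largest negative ones were Gldc (-6.21 ± 0.46), Crhbp (-5.48 ± 0.41), Clgn (-5.37 ± 0.15), Vat1l (-4.69 ± 0.22), Tenm4 (-4.45 ± 0.74) and Syndig1l (-3.91 ± 0.22). The call of S100a6 ended without any 1 of the 8 libraries but replicate 2 of the deficient cultures lacking CXCL12, and that of Scand1 without any 1 of 4 (adjusted p 0.0501 to 0.34). Rpl3l was 1.71 without replicate 1 of the deficient cultures lacking CXCL12.

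In all, the responses of 3750 genes differed by genotype, 1950 more positive and 1800 more negative in sufficient cultures. The split turned without genes that have named copies (1496 and 2193), without the 4 Gapdh-high libraries (953 and 1653), with the 8 libraries fitted alone (473 and 826) and with close pairs summed (382 and 701). The count was 8377 without replicate 2 of the deficient cultures lacking CXCL12 and 1990 without replicate 2 of those with it. It was 2140 and 2131 without replicates 1 and 2 of the sufficient cultures lacking CXCL12, and 2181 and 2251 without those with it. More were negative without any 1 of the 8 libraries but replicate 2 of the deficient cultures lacking CXCL12.

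**Figure D3:**
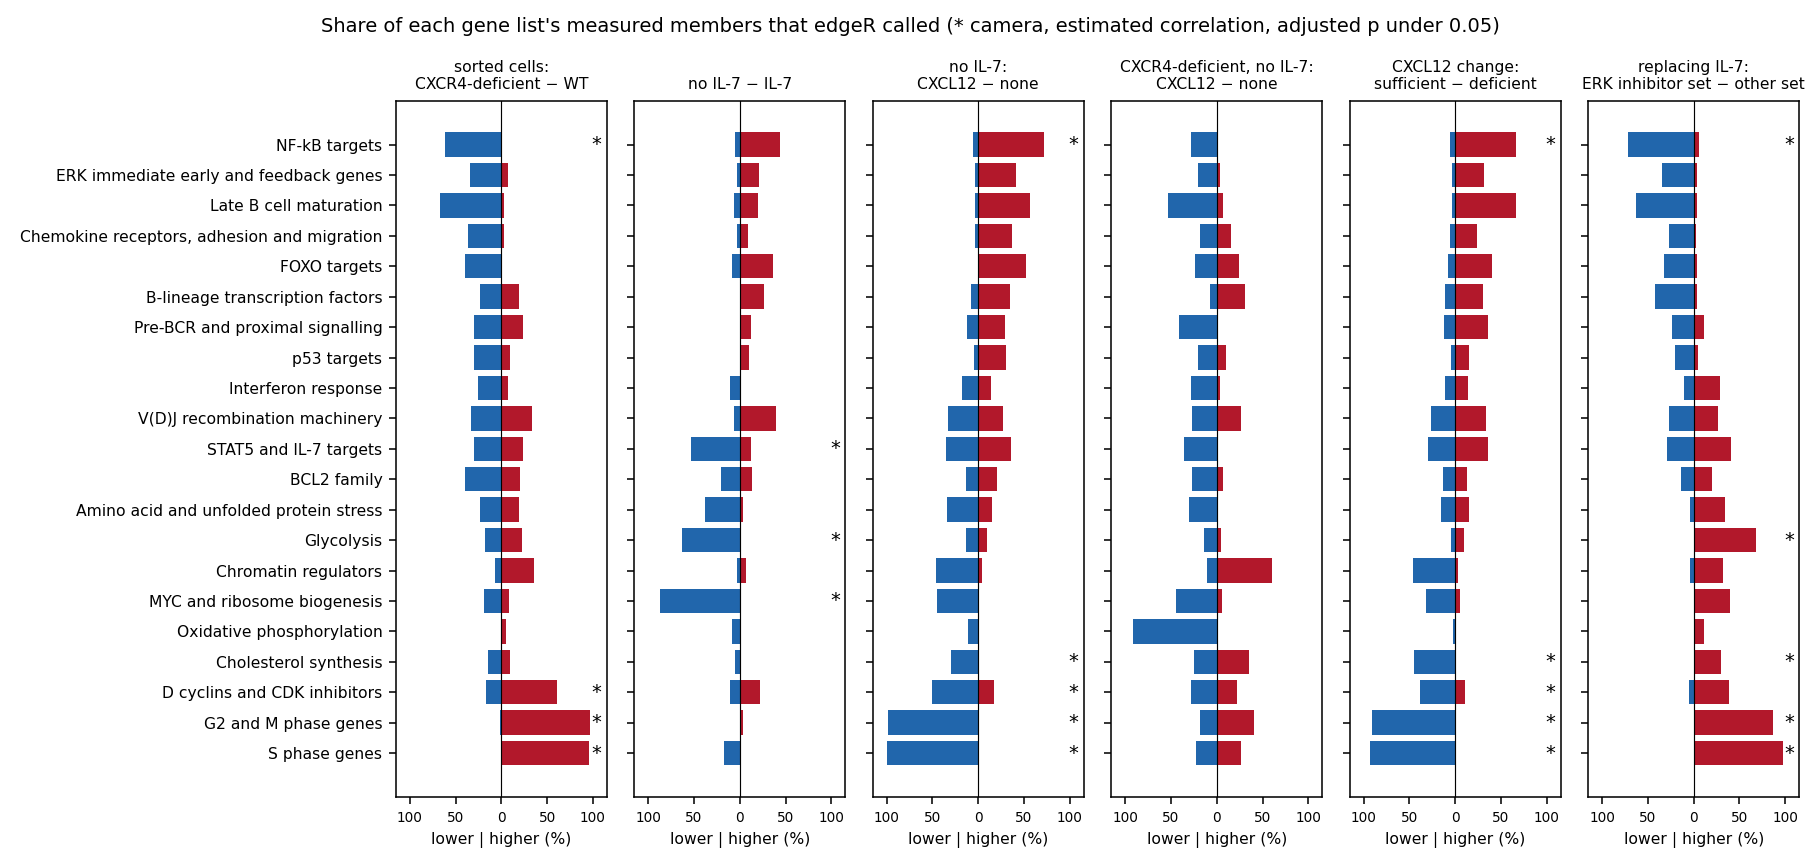
Percent of the measured members of 21 gene lists that edgeR called higher (right, red) or lower (left, blue) in 6 comparisons, with 2 libraries per group and asterisks for lists that camera called at an adjusted p under 0.05 with an estimated correlation. S phase and G2 and M phase genes are nearly all higher in sorted cells labelled CXCR4-deficient and nearly all lower with CXCL12 in cultures without IL-7.

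CXCL12 was also given with IL-7 present. These libraries belonged to the Gapdh-high set and their controls did not, so the effect of CXCL12 and the set cannot be told apart. Rag2 (0.65 ± 0.08) and Cish (0.47 ± 0.10) were higher. Rag1 (81.7 ± 0.367 against 99.4 ± 9.26 CPM, log2 change -0.28 ± 0.25, adjusted p = 0.43) did not pass. Spib (-0.84 ± 0.08) and Brwd1 (-0.84 ± 0.10) were lower. The largest rises were Xist (11.09 ± 1.63), Rps29 (10.74 ± 0.42) and Rpl24 (9.62 ± 0.33). The largest falls were Hspg2 (-6.33 ± 0.34), Bgn (-6.20 ± 0.29) and Fbln2 (-6.14 ± 0.32), matrix genes of stromal cells. Stromal markers gave 0 higher and 12 lower of 14, myeloid markers 17 and 0 of 20, megakaryocyte markers 6 and 0 of 7, NK cell markers 9 and 0 of 10 (adjusted p = 0.049) and T cell markers 10 and 1 of 14 (0.045). RNA quality genes gave 4 and 0 of 10 (0.049). Camera calls were lost for MYC and ribosome biogenesis genes 18 and 0 of 38 [19 and 0] (adjusted p = 0.14) and G2 and M phase genes 22 and 1 of 54 [28 and 1] (adjusted p = 0.14). They were lost too for interferon response genes 17 and 1 of 28 [18 and 1] (adjusted p = 0.14) and p53 targets 2 and 8 of 20 [2 and 10] (adjusted p = 0.14). In all 4720 genes were called, 2271 higher and 2449 lower, and 3055, 3156 and 3119 without replicate 1 or 2 with IL-7 alone or replicate 2 with both factors. The split turned without a filter (2421 and 2035), with these libraries fitted alone (4173 and 4065), with close pairs summed (1828 and 1797) and at 2-fold or more (1319 and 1278).

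The response to CXCL12 without IL-7 was then set against the response with IL-7, a difference that also crosses the sets. It was positive for Rag1 (1.35 ± 0.35), Irf4 (1.16 ± 0.13), Spib (1.72 ± 0.12), Brwd1 (2.11 ± 0.15), Il2ra (2.20 ± 0.14), Bcl6 (1.47 ± 0.25), Egr1 (2.75 ± 0.63), Dusp6 (2.20 ± 0.23) and Ccnd1 (4.93 ± 0.52). It was negative for Myc (-1.88 ± 0.11), Ccnd3 (-1.52 ± 0.17), Mki67 (-1.49 ± 0.20) and Cish (-3.16 ± 0.14). The call of Rag1 ended with close pairs summed. Lists gave, more positive and more negative, S phase genes 0 and 44 of 45 [0 and 45] (adjusted p = 0.0017) and G2 and M phase genes 0 and 53 of 54 [0 and 54] (adjusted p = 0.0026). Growth lists were MYC and ribosome biogenesis genes 0 and 22 of 38 [0 and 25] (adjusted p = 0.04) and cholesterol synthesis genes 0 and 7 of 20 [0 and 7] (adjusted p = 0.04). T cell markers gave 0 and 13 of 14 (adjusted p = 0.014), NK cell markers 0 and 6 of 10, megakaryocyte markers 0 and 6 of 7, myeloid markers 0 and 7 of 20, stromal markers 12 and 0 of 14 and mature B cell markers 7 and 0 of 13. The differences of 5612 genes were called, 3057 positive and 2555 negative, turning without a filter (2619 and 2653) and without genes that have named copies (2636 and 2702).

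To examine the ERK pathway downstream of CXCR4, cultures with CXCL12 and the ERK inhibitor were compared with cultures with CXCL12 alone (n = 2 each, again across the sets). Rag1 (187 ± 3.73 against 431 ± 3.87 CPM, log2 change -1.21 ± 0.25, adjusted p = 0.0013), Irf4 (218 ± 0.0724 against 737 ± 21.6 CPM, log2 change -1.76 ± 0.10, adjusted p = 2.7e-08) and Il2ra (-2.38 ± 0.10) were lower. Myc (72.9 ± 0.72 against 26.4 ± 1.75 CPM, log2 change 1.46 ± 0.08, adjusted p = 2.4e-08), Ccnd3 (1.71 ± 0.13) and Mki67 (1.21 ± 0.14) were higher. Of the genes that ERK induces, 1 of 29 ERK immediate early and feedback genes were higher and 22 lower [1 and 22] (adjusted p = 0.084). Examples were Egr1 (-3.57 ± 0.49) and Dusp6 (-2.87 ± 0.17). Called lists were S phase genes 45 and 0 of 45 [45 and 0] (adjusted p = 0.0039) and G2 and M phase genes 54 and 0 of 54 [54 and 0] (adjusted p = 0.0075). Further called lists were MYC and ribosome biogenesis genes 31 and 1 of 38 [33 and 1] (adjusted p = 0.039), cholesterol synthesis genes 12 and 0 of 20 [12 and 0] (adjusted p = 0.036) and NF-kB targets 4 and 12 of 18 [4 and 12] (adjusted p = 0.039). They included Nfkbie (-2.30 ± 0.09) and Birc3 (-1.89 ± 0.09). Rps29 (11.67 ± 0.46), Xist (10.40 ± 1.60) and Gapdh (10.33 ± 0.23) led the rises and Fat1 (-7.89 ± 0.32), Col6a3 (-7.60 ± 0.30), Col6a1 (-7.42 ± 0.34) and Fosb (-7.35 ± 0.73) the falls. Stromal markers stood beside them with 0 higher and 12 lower of 14, myeloid markers with 15 and 0 of 20, T cell markers with 12 and 0 of 14 (adjusted p = 0.035), NK cell markers with 9 and 1 of 10, megakaryocyte markers with 6 and 0 of 7 and mature B cell markers with 3 and 9 of 13. In all 8460 genes were called, 3994 higher and 4466 lower. The split turned without a filter (4216 and 4125), with these libraries fitted alone (6027 and 5898) and without genes that have named copies (4556 and 3737).

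Each of the 2 sets of CXCR4-sufficient cultures held cultures with IL-7. The change on removing it was taken within a set, a choice made after the data were seen. Comparing these changes still compares the sets. In the Gapdh-high set, which held CXCL12 throughout, the ERK inhibitor replaced IL-7, and in the other CXCL12 did. The difference is thus the inhibitor's change minus that of CXCL12 with IL-7. Log2 changes in the former and the latter set differed for Irf4 (0.13 and 1.68, difference -1.55 ± 0.13), Il2ra (-0.51 and 1.31, difference -1.82 ± 0.14), Bcl6 (0.28 and 2.26, difference -1.98 ± 0.25) and Dusp6 (0.15 and 1.92, difference -1.77 ± 0.23). They differed likewise for Myc (-1.35 and -2.61, difference 1.25 ± 0.11), Ccnd3 (-0.08 and -1.56, difference 1.49 ± 0.17), Mki67 (-0.08 and -1.16, difference 1.09 ± 0.20) and Cish (-1.22 and -4.06, difference 2.84 ± 0.14). For Rag1 the difference was -0.93 ± 0.35 and did not pass (adjusted p = 0.086), nor did that of Egr1, at -1.75 ± 0.64 (adjusted p = 0.075). Rag2 (-0.52 ± 0.11), Irf8 (-0.87 ± 0.12), Foxo1 (-0.69 ± 0.13), Spib (-1.22 ± 0.12) and Brwd1 (-1.49 ± 0.15) had negative differences, and Ccnd2 (1.23 ± 0.25) a positive one. Called lists, with members positive and negative, were S phase genes 44 and 0 of 45 [45 and 0] (adjusted p = 4.4e-04) and G2 and M phase genes 47 and 0 of 54 [51 and 0] (adjusted p = 0.0018). Others were NF-kB targets 1 and 13 of 18 [1 and 14] (adjusted p = 0.0018), glycolysis genes 15 and 0 of 22 [15 and 0] (adjusted p = 0.022) and cholesterol synthesis genes 6 and 0 of 20 [6 and 0] (adjusted p = 0.022). Calls were lost for ERK immediate early and feedback genes 1 and 10 of 29 [1 and 15] (adjusted p = 0.1), late B cell maturation genes 1 and 19 of 30 [1 and 19] (adjusted p = 0.051) and B-lineage transcription factors 1 and 11 of 26 [1 and 12] (adjusted p = 0.18). Mature B cell markers gave 0 and 9 of 13 (adjusted p = 0.041) and RNA quality genes 0 and 4 of 10. Inside the former and the latter set, stromal markers gave 9 higher and 0 lower and 12 and 0 of 14, myeloid markers 7 and 0 and 16 and 0 of 20, and mature B cell markers 2 and 2 and 9 and 0 of 13. Camera called these but for the mature B cell markers of the former, and none with an estimated correlation. The differences of 2952 genes were called, 1507 positive and 1445 negative, and fewer without any 1 library. The call of Rag2 ended without replicate 1 with both factors.

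CXCR4-deficient cultures were compared with CXCR4-sufficient ones, which also crosses the sets. Without IL-7, Irf4 (-0.79 ± 0.10) and Brwd1 (-1.96 ± 0.11) were lower, and Myc (1.31 ± 0.08) and Cish (2.10 ± 0.10) higher. Rag1 (96.5 ± 49.9 against 206 ± 1.36 CPM, log2 change -1.10 ± 0.25, adjusted p = 0.0022) was lower, at -0.71 and -1.75 without replicates 1 and 2 of the deficient cultures. The calls of Irf4 and Rag1 ended with the 4 libraries fitted alone. With CXCL12, Rag1 (179.7 ± 26.2 against 431 ± 3.87 CPM, log2 change -1.26 ± 0.25, adjusted p = 7.9e-04) and Irf4 (-1.54 ± 0.10) and Dusp6 (-4.62 ± 0.19) were lower. Myc (2.87 ± 0.08) and Mki67 (1.32 ± 0.14) were higher. Without IL-7 camera calls were lost for MYC and ribosome biogenesis genes 34 and 0 of 38 [34 and 0] (adjusted p = 0.053) and S phase genes 33 and 2 of 45 [33 and 2] (adjusted p = 0.053). So were those for STAT5 and IL-7 targets 10 and 2 of 17 [10 and 2] (adjusted p = 0.053) and late B cell maturation genes 6 and 21 of 30 [6 and 22] (adjusted p = 0.32). With CXCL12 they held for S phase genes 45 and 0 of 45 [45 and 0] (adjusted p = 0.0027), G2 and M phase genes 54 and 0 of 54 [54 and 0] (adjusted p = 0.0062) and NF-kB targets 1 and 15 of 18 [1 and 15] (adjusted p = 0.02). They were lost for late B cell maturation genes 1 and 27 of 30 [1 and 28] (adjusted p = 0.055). Stromal markers gave 0 and 13 of 14 in both, myeloid markers 0 and 18, then 0 and 19 of 20, and mature B cell markers 0 and 9, then 0 and 12 of 13. There were 9743 calls without IL-7, 4601 higher and 5142 lower, but 634 higher and 1922 lower with the 4 libraries fitted alone. With CXCL12 there were 9366, 4057 higher and 5309 lower.

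Counts at the Igk joining segments were followed, a choice made after the table was seen. The 5 IgkJ segments summed to 237 ± 6.96 CPM in sorted wild-type cells and 88.4 ± 0.615 CPM in sorted cells labelled CXCR4-deficient (n = 2 each). All 5 fell, with IgkJ1 at 17.3 ± 0.625 against 47.0 ± 0.383 CPM (log2 change -1.45 ± 0.13, adjusted p = 5.9e-06). In culture the sum was 12.7 ± 1.36 CPM with IL-7, 22.9 ± 0.556 without IL-7 and 80.7 ± 3.45 without IL-7 with CXCL12. Of the 5 segments, IL-7 withdrawal gave 2 higher and 0 lower and CXCL12 without IL-7 5 higher and 0 lower, with IgkJ1 at 21.7 ± 0.824 against 7.62 ± 0.092 CPM (log2 change 1.51 ± 0.14, adjusted p = 6.4e-06). With both factors the sum was 24.6 ± 0.836 CPM, with the ERK inhibitor 17.7 ± 0.954, and in CXCR4-deficient cultures 12.1 ± 6.50 without and 13.5 ± 0.728 with CXCL12. CXCL12 with IL-7 gave 4 higher and 0 lower, the difference by IL-7 2 and 0 and that by genotype 4 and 0, the ERK inhibitor with CXCL12 0 and 5, and the within-set difference 0 and 5. Of 118 Igkv segments, which share reads with their relatives and are uncertain one by one, sorted cells gave 0 higher and 94 lower, IL-7 withdrawal 22 higher and 0 lower and CXCL12 without IL-7 83 higher and 1 lower. The numbers were for CXCL12 with IL-7 44 higher and 1 lower, the difference by IL-7 26 and 8, the ERK inhibitor 9 and 74, CXCL12 in deficient cells 3 and 4, the difference by genotype 38 and 1 and the within-set difference 0 and 68. Igkc, the kappa constant gene, was not analysed here. Counts at IgkJ hold unrearranged and rearranged transcripts alike, which the table does not separate.

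**Figure D4:**
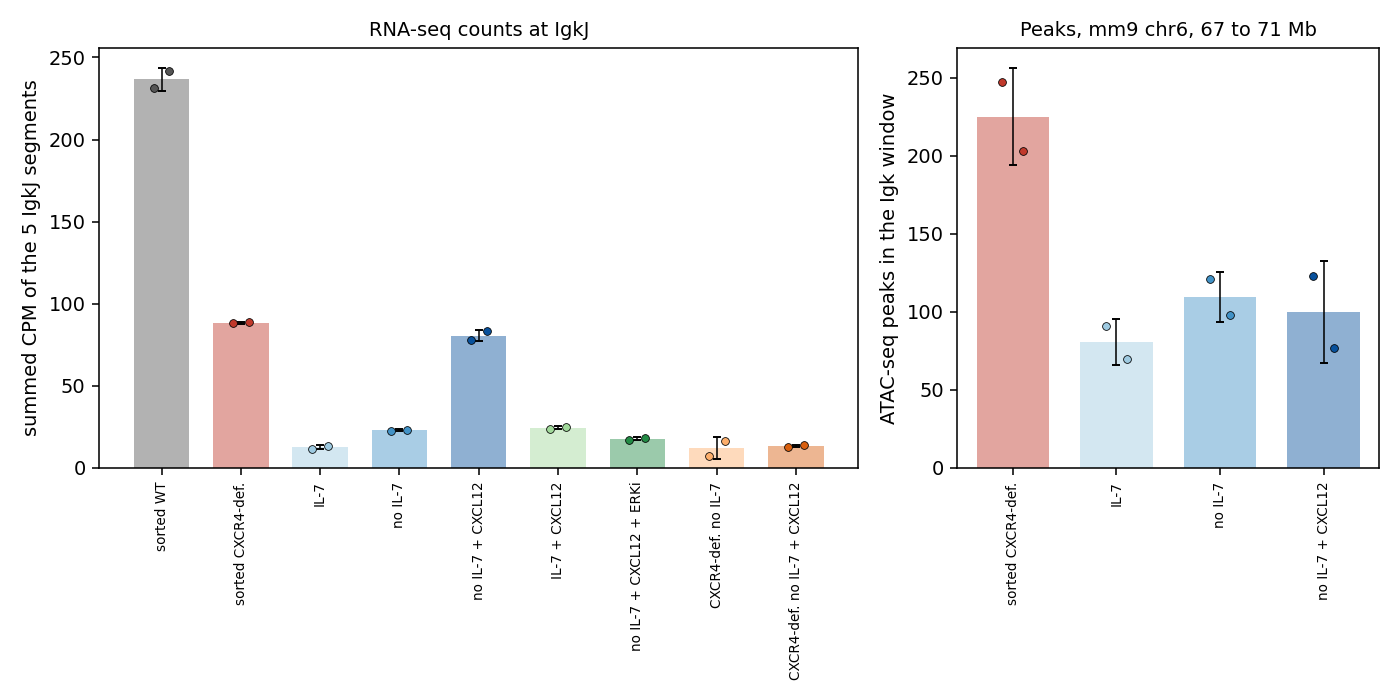
Left, summed CPM of the 5 IgkJ segments in 9 groups of RNA-seq libraries, and right, deposited ATAC-seq peaks between 67 and 71 Mb of mm9 chromosome 6, which holds Igk, in 4 groups, with bars for means, points for the 2 libraries of a group and error bars for SD. IgkJ counts are highest in sorted wild-type cells and, among cultures, without IL-7 with CXCL12, and the peaks are most numerous in sorted cells labelled CXCR4-deficient.

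The changes with CXCL12 without IL-7 were set against those of other comparisons across 14862 genes, which are not independent replicates. Against the difference of sorted cells labelled CXCR4-deficient from wild type, Pearson's r was -0.227 and Spearman's rho -0.307. Of the genes called in both, 1021 were higher in sorted cells labelled CXCR4-deficient and lower with CXCL12, against 326 for independent lists, and 853 lower and higher, against 453. There were 260 genes higher in both, against 426, and 137 lower in both, against 347. These comparisons share no library, and unchanged groups in 20 simulated draws gave a mean r of 0.00186. Without replicate 1 of the cultures with CXCL12 r was -0.127. The response to CXCL12 in deficient cultures gave r = 0.0472 and rho = 0.0739, with a simulated r of -0.0102, and r was -0.00876 without replicate 2 of the deficient cultures with CXCL12. The response with IL-7 gave r = -0.112 and rho = -0.185, with r at -0.0558 without replicate 2 with IL-7. The ERK inhibitor comparison shares libraries with that of CXCL12: r was -0.511 and rho -0.608 against a simulated r of -0.554, and the covariance -0.837 against a simulated -0.0839. IL-7 withdrawal gave r = 0.263 and rho = 0.454 against a simulated r of -0.478, with a covariance of 0.144 against -0.0686. With 2 libraries per group the shared controls were not split, and part of these values may come from them. The shared libraries differ by little more than counting noise, for which the simulated values may be too negative. For IL-7 withdrawal r was 0.149 without replicate 1 with IL-7, 0.0945 without replicate 2 lacking IL-7, 0.154 without replicate 2 with CXCL12 and, without replicate 1 lacking IL-7, -0.00161.

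Accessible regions were compared between the cultures by overlap of the deposited peaks, with 2 libraries per group and no p-value. Of 48400 regions from the cultures with and without IL-7, 26085 had a peak in all 4 libraries, 2041 in both libraries without IL-7 and neither with it, and 573 in both with IL-7 and neither without it. These 2614 regions stand beside 2446 for the split by replicate number and 1140 for the other, so the condition parted the lists little more than the number did. Of 47456 regions from the cultures without IL-7, 26044 had a peak in all 4 libraries, 253 in both with CXCL12 alone and 1819 in both without it alone, 2072 in sum, below the 2444 of the split by replicate number. Lists of replicate 1 were longer than those of replicate 2 in each group. With lists of equal length the numbers were 1048 without IL-7 alone and 974 with it alone, and 625 with CXCL12 alone and 722 without it alone. When the sorted libraries were merged in, 1561 of 2020 regions found without IL-7 alone (77.3%) had a peak in both of them, against 143 of 572 found with IL-7 alone (25.0%). Without chromosomes 10 to 12 these shares were 83.7% and 30.1%. Ranked by the lower of its libraries' scores, which are the authors' own, the first of the regions found without IL-7 alone lay within the Igk window (scores 22.6 and 19.8). The 6 cultured lists held an excess of peaks at the start of chromosome 10.

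The Igk window, from 67 to 71 Mb of mm9 chromosome 6, held 225 ± 31.1 peaks in sorted cells labelled CXCR4-deficient (mean ± SD, n = 2), 80.5 ± 14.8 with IL-7, 109.5 ± 16.3 without IL-7 and 100 ± 32.5 without IL-7 with CXCL12. There were 17 regions with a peak in both libraries without IL-7 and neither with it, against 2 the other way. Between cultures with and without CXCL12 the numbers were 1 and 3. Both libraries without IL-7 (121 and 98 peaks) lay above both with it (91 and 70), and those with CXCL12 (123 and 77) overlapped either group. Peak numbers depend on list length, and with lists of equal length the window held 109.5 peaks in sorted cells, 70.5 with IL-7, 85.5 without IL-7 and 93.5 with CXCL12.

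**Figure D5:**
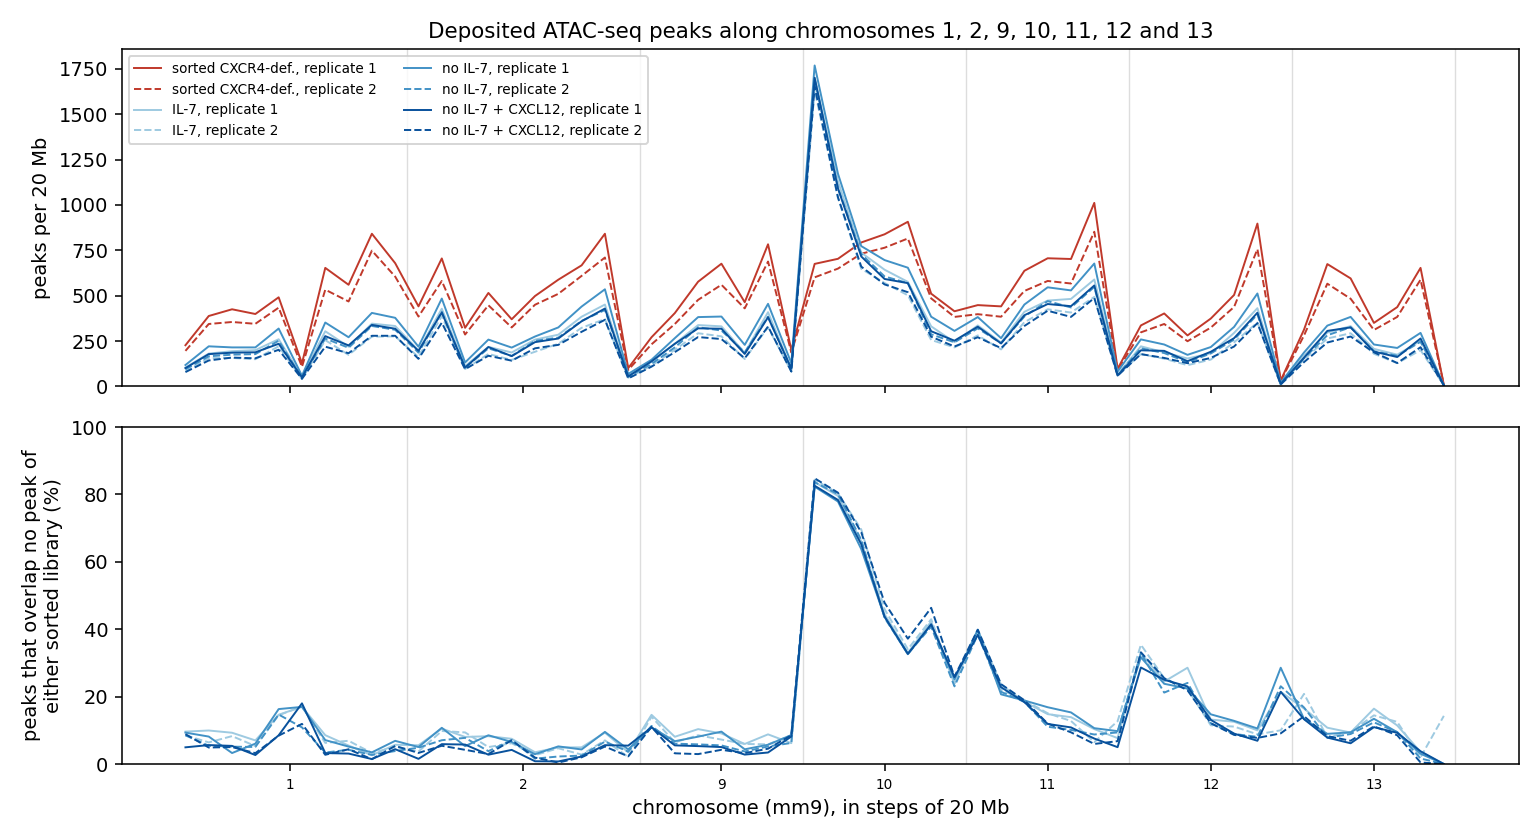
Deposited ATAC-seq peaks per 20 Mb (top) and the percent of them that overlap no peak of either sorted library (bottom) along mm9 chromosomes 1, 2 and 9 to 13, 1 line per library and a shorter last step on each chromosome. The 6 cultured libraries exceed the sorted ones at the start of chromosome 10, and their excess declines into chromosome 12.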

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

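Of the tests weighed here, those of a CXCL12 effect on the copied genes, of a gain of chromosome 10, of the peak numbers before removal and of a wrong label were chosen only after the result was seen.

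The response to CXCL12 without IL-7 differed between CXCR4-sufficient and CXCR4-deficient cultures for 3750 genes by edgeR's test of the difference (n = 2 each). Log2 differences, sufficient minus deficient, were 0.57 for Rag2, 0.75 for Irf4, 0.45 for Irf8, 0.99 for Pax5, 0.81 for Spib, 0.89 for Brwd1, 1.5 for Il2ra, 1.61 for Bcl6 and 1.47 for Dusp6. They were -1.56 for Myc, -1.40 for Ccnd2, -0.93 for Ccnd3, -2.05 for Mki67 and -2.43 for Cish. The count was 1990 to 8377 without 1 library, 1299 with these 8 libraries fitted alone and 1083 with close pairs summed. The calls of Irf8 and Pax5 ended without any 1 sufficient library and those of Rag2, Irf4, Irf8, Pax5 and Ccnd3 with the 8 libraries fitted alone. Genotype and set of libraries cannot be told apart, and cell stage as labelled goes with genotype in part.

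The response to CXCL12 differed between cultures without and with IL-7 for 5612 genes by the same test, and because the cultures with both factors belong to the 4 libraries of the next paragraph, an effect of IL-7 and one of the set of libraries cannot be told apart. Log2 differences, without minus with IL-7, were 1.35 for Rag1, 1.16 for Irf4, 0.55 for Irf8, 0.88 for Foxo1, 1.29 for Ikzf3, 1.72 for Spib, 2.11 for Brwd1, 4.93 for Ccnd1, 2.20 for Il2ra, 1.47 for Bcl6, 2.75 for Egr1 and 2.20 for Dusp6. They were -1.88 for Myc, -0.73 for Ccnd2, -1.52 for Ccnd3, -1.49 for Mki67 and -3.16 for Cish. The call of Ccnd2 ended without any 1 of the 8 libraries (adjusted p 0.063 to 0.11), and that of Ikzf3 without any but replicate 2 with IL-7 (adjusted p 0.056 to 0.088). Those of Rag1, Ikzf3 and Ccnd2 ended with close pairs summed.

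A set of 33 genes, Gapdh, Rps29 and other ribosomal protein genes among them, summed to 28351 CPM in the 4 libraries with IL-7 and CXCL12 or with the ERK inhibitor and to 253 CPM in the other 14, membership having been set after the data were seen. Of them 72.7% had a named pseudogene, against 5.89% of other genes at 100 CPM or more in the 4 libraries. The median log2 shift of all genes between these 4 libraries and the other cultures rose with the number of named pseudogenes, from -0.11 with none to 3.28 with 4 or more, a difference of 3.39. Whether CXCL12 raised them cannot be told from their median log2 change of -0.014 without IL-7, since low counts in those libraries were part of how they were chosen. A candidate explanation that stays open is that reads matching several copies were counted in these 4 libraries and dropped in the others, no biological one having been excluded.

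The 6 cultured ATAC-seq lists held an excess of peaks from the start of chromosome 10 into chromosome 12, and their first 20 Mb of chromosome 10 had 7.32 to 10.2 times the peaks of a mean 20 Mb of chromosome 1. A gain of chromosome 10 is argued against by RNA libraries of the same conditions, in which its genes lay 0.0032 log2 above the other autosomes against the 0.58 of 3 copies for 2. A less strict removal of peaks there met the bound set beforehand, a kept share at least 1.3 times that of chromosome 1, at 1.32 to 1.36 times, which could account for a small part. It is argued against as the whole cause, because the peak numbers before removal were already in excess by 5.57 to 7.53 times. What remains is open and untested, and chromosomes 10 to 12 follow chromosome 1 in the order of the lists.

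The second sorted library labelled CXCR4-deficient held 409 CPM of Cxcr4, against 37.2 in the first. Wild-type cells mixed in at the share of 0.415 that Cxcr4 needs are argued against, since 92 S, G2 and M phase genes lay at a median share of 0.142 (quartiles 0.088 and 0.197). A wild-type library under a wrong label is argued against by a median log2 difference from wild type of 1.32 over 99 such genes. Incomplete deletion, or reads from an undeleted part of the gene, may remain as an explanation and was not tested.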

How the results depend on the processing

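Of the alternatives, those with close pairs summed, without genes with named copies, without the 4 Gapdh-high libraries, within sets of libraries and without chromosomes 10 to 12 were chosen after the data were seen. With 2 libraries per group, calls rest on a spread pooled over all groups, a lone library left by an omission is assumed to vary like the others, and the cause of a change below was not tested unless given.

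Called genes, in the order sorted cells, IL-7 withdrawal, CXCL12 without IL-7, CXCL12 with IL-7, ERK inhibitor, CXCL12 in deficient cells, CXCR4 loss without and with CXCL12, and the differences by genotype and by IL-7, numbered at 2-fold or more 2337, 390, 1865, 2597, 4735, 1266, 5423, 5689, 1955 and 3545. Without 1 library in turn they ranged over 3137 to 4686, 589 to 851, 2257 to 2573, 3055 to 3168, 6542 to 6974, 0 to 8602, 8179 to 11038, 7848 to 8228, 1990 to 8377 and 4250 to 4530. With only the groups compared, IL-7 withdrawal had 7299, CXCL12 without IL-7 10790 and with IL-7 8238, CXCR4 loss without CXCL12 2556, and the differences by genotype 1299 and by IL-7 10079. DESeq2 called 2676 for IL-7 withdrawal. With close pairs summed the counts were 355 for IL-7 withdrawal, 1149 for CXCL12 without IL-7, and 1083 and 3299 for the differences by genotype and by IL-7. Without the 4 libraries IL-7 withdrawal had 1069. The ERK inhibitor's difference within sets had 2952 (1827 to 2056 without 1 library).

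CXCL12 in deficient cells had 0 edgeR calls with only the groups compared (261 genes at an unadjusted p under 0.05), with close pairs summed (5929), without the 4 libraries (6079) and without replicate 2 of the deficient cells with CXCL12 (4040), against 6302 DESeq2 calls on all libraries.

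The replicate block gave 5006, 1650, 4410, 4607, 8392, 4997, 9675, 9336, 3665 and 5524 called genes in the order above and 108 called lists. The deviations of libraries of the same number correlated with r from -0.014 to 0.215. No label names a shared animal or batch, so the numbers were not taken as pairs.

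Called gene lists fell from 109 of 210 to 30 with an estimated correlation and ranged from 102 to 114 without 1 library. Correlations of the log2 changes of CXCL12 without IL-7 ranged without 1 library from -0.251 to -0.127 with CXCR4 loss in sorted cells, -0.125 to -0.0558 with CXCL12 with IL-7 and -0.581 to -0.463 with the ERK inhibitor. The one with CXCL12 in deficient cells ran from -0.00876, without replicate 2 of those with CXCL12, to 0.0907. The one with IL-7 withdrawal was 0.393 at 1 CPM in 2 libraries and ran from -0.00161, without replicate 1 without IL-7, to 0.288.

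Of the named changes that were not called, 10 passed with DESeq2, 4 with RLE, 3 without a filter, 3 without genes with named copies and 19 with only the groups compared. Uncalled log2 changes turned for Rag2 in sorted cells (0.04 to -0.031 with RLE and -0.031 with DESeq2) and, with CXCL12, for Id3 (0.03 to -0.0016 without a filter, -0.067 with only the groups compared, -0.074 without genes with named copies and -0.062 without the 4 libraries) and Ikzf1 (0.09 to -0.0037 with only the groups compared and -0.012 without genes with named copies). Without 1 library the difference by genotype ran from -0.51 to 1.19 for Vpreb1, -0.49 to 0.51 for Rag1, -3.56 to 1.79 for Ccnd1 and -0.063 to 0.23 for Il7r, the lowest without replicate 1 (Vpreb1) or 2 of deficient cells without CXCL12.

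Regions with a peak in both libraries of 1 group alone, without IL-7 and with it, numbered 884 and 172 in the higher-scoring part of each list and 1048 and 974 in lists of equal length. With CXCL12 and without, they numbered 29 and 715, and 625 and 722, with 457 for CXCL12 at an overlap of 50% and 119 without chromosomes 10 to 12. Without 1 library, presence then resting on a lone library, they ranged over 2759 to 7432 and 902 to 2913, and over 552 to 2066 and 2726 to 7974. Mean peaks at Igk in the higher-scoring part were 111 in sorted cells, 32.5 with IL-7, 55 without and 38 with CXCL12. Without 1 library they were 203 to 247, 70 to 91, 98 to 121 and 77 to 123.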

Other observations

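All values of this part were chosen after the data were seen.

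The sorted cells labelled CXCR4-deficient were the only sorted group with ATAC-seq, and their 2 peak lists overlapped each other by a Jaccard index of 0.733, against 0.370 to 0.521 with the cultures. With the sorted lists merged in, both held 1211 of 1804 regions in both cultures without IL-7 and neither with CXCL12 (67.1%). Of 250 in both with CXCL12 and neither without it, both held 66 (26.4%). Without chromosomes 10 to 12 these were 1005 of 1353 (74.3%) and 54 of 117 (46.2%). Here too lists were not cut to equal length, and 67.1% may be background.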
